A study of Mus musculus with 12 samples.

How the data were processed

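The series measured mRNA in mouse lung CD11c+ cells with the NanoString nCounter XT assay and its Myeloid Innate Immunity Panel. In this assay a reporter probe with a colour barcode hybridises to each target transcript and the barcodes are counted singly, without sequencing. Per the labels' protocols, lysate equivalent to about 5000 cells (5 µl at 1000 cells per µl) was hybridised for 18 h at 65 °C with the panel's reporter and capture probes. The values deposited for the 12 samples are whole-number counts per probe. The table held 768 probes, of which 754 were endogenous genes, 6 were positive controls and 8 were negative controls. The unit was read from the values: all were whole numbers, the sample totals differed, and the control probes were still present at levels that differed between samples, so the deposited counts had not been scaled to positive controls or to reference genes. No value was 0 and the lowest was 1, so a floor of 1 may have been set before deposit. The counting software, the checks of imaging quality and any such floor are not given in the sources used here.

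Sample groups came from the titles, which name the run (1 or 2), the treatment (recombinant RELMa, here rRELMa, or PBS) and a number from 1 to 3. This gave 4 groups of 3 samples. The labels state neither what separates the runs nor whether the numbered samples came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Replicate pairs within a group were compared with a chi-square test of their counts over the tested genes. All 12 pairs differed by more than sampling noise (chi-square per degree of freedom 1.56 to 3.24, largest p = 2.15e-12), and every sample was counted separately.

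The design, written before the data were examined, named limma for normalized values and edgeR for raw counts. Since the table held raw counts, the main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling over the tested genes. TMM became the main scaling only once the counts were seen to be unscaled, as the design had expected the deposited scaling. Genes entered the test if their mean count over the 12 samples was at least 20. Control probes were left out, and so were the 17 genes on the panel from a list of reference genes written before the data were examined. This left 418 tested genes and 319 below the minimum. The main comparison fitted treatment with the run as a block over all 12 samples. A second fit with 1 coefficient per group gave the effect within each run, the difference of the effects, and run 2 against run 1 in PBS. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. The gene and list tests were two-sided. Printed normalized counts are TMM-scaled counts, with the SD over the 3 samples of a group. The common biological coefficient of variation was 4.96%, with 9 residual and 18.4 prior degrees of freedom. The background limit of a sample was the mean plus 2 SD of its 8 negative controls.

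Gene lists and cell type markers were fixed before the data were examined. They covered alternative activation of macrophages, proinflammatory cytokines and classical activation, CC chemokines, other chemokines, chemokine receptors, interferon-stimulated genes, pattern recognition, NF-kB targets, Fc receptors, antigen presentation, complement, matrix remodelling, lysosome and scavenger receptors, integrins, lipid handling, immediate early genes, the type 2 cytokine axis, T-cell costimulation, and hypoxia and glycolysis. Markers covered alveolar and interstitial macrophages, monocytes, dendritic cells, plasmacytoid dendritic cells, neutrophils, eosinophils, mast cells or basophils, T cells, B cells, NK cells, and epithelial, endothelial or stromal cells. The 20 lists with at least 5 tested genes were tested with limma's camera (preset correlation 0.01), which compares a list with the other tested genes, on edgeR's negative binomial z-scores of the counts. Camera with an estimated correlation and fry stood beside it. For the difference between runs in PBS and for the interaction, camera was added after the data were seen.

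The rule for named genes, also fixed beforehand, took Retnla in every sample, all genes called in the main comparison if 30 or fewer and, with fewer than 10 called, the 10 genes per direction with the smallest unadjusted p as values only. It also took up to 4 members of each list with the smallest unadjusted p, and the 5 genes per direction with the smallest p for the difference between runs. The last part was applied both to the difference of the rRELMa effects and to run 2 against run 1 in PBS. Genes named outside the rule are marked in the text. Of the 754 endogenous symbols, 744 matched current symbols of the GRCm38.p6 gene table, 9 matched as synonyms and 1 was not found. Symbols are printed as in the table.

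The test was checked on simulated counts for the 418 genes and the real sample sizes, with 200 genes changed in each of 20 draws. For the main comparison it recovered 75.8% of genes changed 1.25-fold, 96.5% of those changed 1.5-fold and 99.9% of those changed 2-fold, and 4.1% of its calls were false. With 30 changed genes the recovery was 62.5%, 89.0% and 100.0% at these sizes. Within run 1 the recovery with 200 changed genes was 46.9%, 79.5% and 96.0%, and within run 2 it was 61.3%, 90.1% and 98.0%. A list raised 1.25-fold was called by camera in 20 of 20 draws. In these draws all members rose alike and genes varied independently, so recovery for lists of correlated genes was not measured.

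Alternatives listed beforehand were scaling to the reference genes, to the sample median or by quantiles (with voom), DESeq2 size factors, DESeq2 1.42.0, limma on log2(count + 8), no filter, a minimum of 50, robust fitting in edgeR, voom with sample weights, reference genes included, no run term, each run alone, the runs averaged, a replicate block, and leaving out each sample. Added after the data were seen were library totals without TMM, positive-control scaling, limma with a pseudocount of 1, subtraction of the negative controls, and a filter at the negative-control limit. For run 2 against run 1 in PBS only scaling to the reference genes and by quantiles had been listed beforehand, and its other settings were added. Also added were DESeq2 size factors within runs and for the difference between runs, and leaving out each sample in the list tests.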

Results

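RELMa (resistin-like molecule alpha) is a secreted protein made by alternatively activated macrophages and airway epithelium during helminth infection, and Retnla is its gene. To measure the response of lung myeloid cells to the protein, mice lacking RELMa had been infected with 500 third-stage larvae of the nematode Nippostrongylus brasiliensis, and lungs were taken on day 10. CD11c+ cells, a gate that takes in alveolar macrophages and dendritic cells, were sorted from the dissociated lungs. They were cultured overnight at 37 °C in 10% serum and starved in 1% serum for 1 h by the growth protocol or 2 h by the design text. They then received 500 ng/ml rRELMa or PBS for 4 h. There were 12 samples, 3 for each treatment in each of 2 runs. Total endogenous counts were 179719 to 257415 per sample in run 1 and 411169 to 765719 in run 2. Between 353 and 452 of the 754 genes lay above the background limit of their sample, which was 16.1 to 31.1 counts.

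Retnla, the gene missing in these mice, gave 5 to 18 raw counts in the 12 samples, near the level of the negative-control probes, whose mean was 7.62 to 15 counts per sample. It was below the count minimum and was not tested. The part of the gene its probe covers is not given in the sources used here. All 10 alveolar macrophage markers on the panel passed the count minimum, with mean raw counts from 82.5 for Siglecf, a sialic acid-binding receptor, to 97272 for Chil3, a chitinase-like protein of alternative activation. Chil3 and its close paralog Chil4 together took 34.5% to 36.7% of endogenous counts in run 1 and 40.3% to 43.6% in run 2. Whether their probes tell the paralogs apart is not given, so the split between them is uncertain. Of the dendritic cell markers 9 of 10 passed it, led by Ccr7 at 346, and of the interstitial macrophage markers 9 of 11, led by Csf1r at 735. Of the neutrophil markers 4 of 12 passed, with Mmp8 at 437 but Ly6g at 4.92, and of the epithelial, endothelial or stromal markers 2 of 7, with Cav1 at 1417 but Cdh5 at 16.9. Counts of different probes do not rank the cell types. No marker of T cells (2 on the panel), B cells (2), NK cells (3), or mast cells or basophils (9) reached the mean count of 20. The highest was Cd247 of the T-cell receptor complex at 19.7. With so few lymphocyte markers on the panel, lymphocytes were not shown to be absent.

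Arg1 was lower with rRELMa than with PBS, and it was the one gene called. Arg1 encodes arginase 1, the arginine-degrading enzyme of alternatively activated macrophages. In run 1 its normalized count was 219 ± 16 (SD, n = 3) with PBS and 151 ± 20.1 (SD, n = 3) with rRELMa. In run 2 it was 29.5 ± 0.69 (SD, n = 3) with PBS and 20 ± 0.79 (SD, n = 3) with rRELMa. With the run as a block, Arg1 fell by 31.7% (log2 fold change -0.55, SE 0.10, edgeR quasi-likelihood test, adjusted p = 0.00268) and was lower in 6 of 6 rRELMa samples. In both runs every rRELMa sample lay below every PBS sample after TMM scaling. The raw Arg1 counts in run 2 overlapped, at 26 to 45 with PBS and 27 to 33 with rRELMa. The PBS sample with 26 had the lowest endogenous total of run 2, 411169. All lay above the background limit of their sample (16.1 to 23.9) but near it. With counts this low, the small SDs in run 2 should not be read as the precision of the assay. Without the run in the model Arg1 was no longer called (log2 fold change -0.57, adjusted p = 0.998), and 0 genes were.

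**Figure D1:**
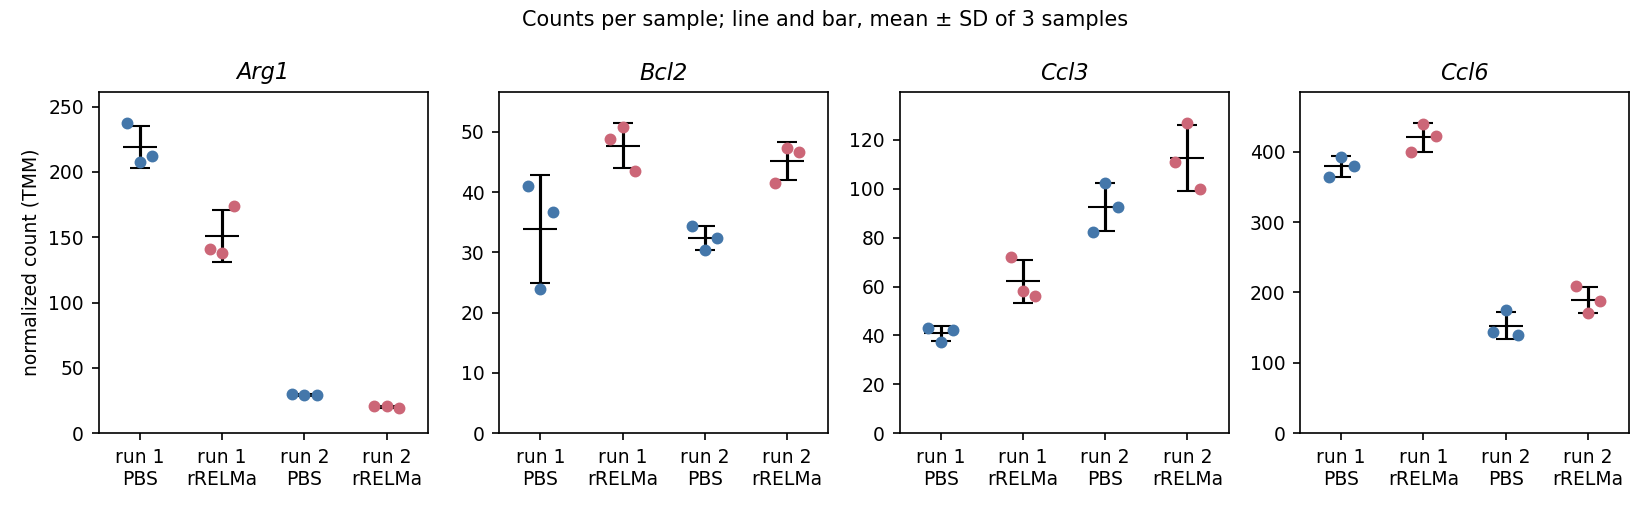
Normalized counts (TMM) of Arg1, Bcl2, Ccl3 and Ccl6 on the vertical axes, with 1 point per sample in the 4 groups of run and treatment, blue for PBS and red for rRELMa. Black lines and bars are the mean ± SD of 3 samples. Arg1 is lower with rRELMa in both runs, at 151 against 219 in run 1 and 20 against 29.5 in run 2. The raw counts of Bcl2 and Ccl3 in run 1 PBS lay near or below background.

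No other gene of the 418 passed the adjustment, limma with a pseudocount of 1 and DESeq2 also called Arg1 alone, and 33 had an unadjusted p under 0.05, where chance gives 20.9. No gene differed by 1.5-fold or more between treatments in the main comparison, and the median absolute log2 fold change was 0.06. The smallest unadjusted p on the positive side belonged to Bcl2, an inhibitor of apoptosis, with a log2 fold change of 0.49 (SE 0.13, adjusted p = 0.173, edgeR), higher in 6 of 6 rRELMa samples. Next came the chemokine genes Ccl3 at 0.36 (SE 0.10, adjusted p = 0.268) and Ccl6 at 0.22 (SE 0.07, adjusted p = 0.311), each higher than the PBS mean of the same run in 6 of 6 samples, with single samples overlapping in run 2. In run 1 PBS the raw counts of Bcl2 and Ccl3 lay near or below the background limit of their sample (23.7 to 31.1). The fold changes of these genes are uncertain for that reason. Emp1, Grn, Itgb1, Ctsl, Ccr7, Tm7sf3 and Btg2 followed, with log2 fold changes from 0.11 for Itgb1 to 0.34 for Tm7sf3 and adjusted p of 0.629 or more. On the negative side, after Arg1, stood Cxcr4 (-0.18), Cyp1b1 (-0.48), Mif (-0.10), Fabp4 (-0.14), Tnfrsf1b (-0.10), Icam1 (-0.29), Pik3cg (-0.21), Acad10 (-0.38) and Hpgds (-0.38), again with adjusted p of 0.629 or more. These are values of genes that did not pass the test. In both runs, 6 genes had their 3 rRELMa samples on the same side of all 3 PBS samples, where chance gives 2.09 of 418 (0.5%), and 3 genes were separated in opposite ways in the runs, with the same chance value. Within single runs 52 genes in run 1 and 64 in run 2 were separated, where chance gives 41.8 (10%). The 6 were Arg1 and Sgpp1 on the lower side and Bcl2, Ikzf1, Itgb1 and Vamp2 on the higher side. Ikzf1, Sgpp1 and Vamp2 were named after their values were seen.

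Gene lists showed little else. Of the 17 tested genes of alternative activation, Arg1 fell and 16 did not pass the test, also when adjusted over the list alone. Among these were the mannose receptor Mrc1 (log2 fold change 0.09), the eosinophil attractant Ccl24 (0.13) and Chil4 (0.07). Of the 9 CC chemokine genes, 0 passed over all genes and 2, Ccl3 and Ccl6, passed when adjusted over the list alone. Ccl6 also passed over the 10 alveolar macrophage markers alone, and no other list had a gene that did. Camera called 0 of the 20 lists, with 3 at an unadjusted p under 0.05. These were CC chemokines (median log2 fold change 0.09, adjusted p = 0.177), interstitial macrophage markers (-0.06, adjusted p = 0.177) and lipid handling (-0.03, adjusted p = 0.177). With an estimated correlation 0 lists were called. Fry's directional test also called 0. Its smallest p was that of T-cell costimulation, where 8 of 8 genes had positive values (median 0.10, adjusted p = 0.0782), although 6 of 8 did after library-total, quantile or DESeq2 size factor scaling and 7 of 8 after scaling to the median. Fry's mixed test, which asks whether members change in either direction, called 3 lists. They were alternative activation (adjusted p = 0.00202), integrins and adhesion (adjusted p = 0.034) and alveolar macrophage markers (adjusted p = 0.0438). In the alternative activation list Arg1 was the 1 gene of 17 with an unadjusted p under 0.05, and the list was not tested without it.

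The remaining lists held no called gene. The 11 proinflammatory genes had a median log2 fold change of 0.09, with Tnf at 0.12 and the interferon-inducible chemokine Cxcl9 at -0.24. The 11 interferon-stimulated genes had a median of -0.03, with Irf1 at 0.18 and Mx1 at -0.20. The 9 NF-kB targets had a median of 0.01, the 17 pattern recognition genes 0.04, the 17 antigen presentation genes 0.02 and the 7 complement genes -0.02. The 14 matrix remodelling genes had a median of 0.01, the 11 lysosome and scavenger genes -0.04 and the 13 integrin and adhesion genes 0.01. The 11 immediate early genes had a median of 0.05, the 5 genes of the type 2 axis 0.05, the 6 chemokine receptors -0.03 and the 6 CXC, CX3C and XC chemokines -0.05. Dendritic cell markers had a median of 0.05 over 9 genes. Too few genes for a list test were left for Fc receptors (4, median -0.03), monocyte markers (4, median -0.14), neutrophil markers (4, median -0.01), and hypoxia, plasmacytoid dendritic cell, eosinophil and epithelial markers (2 each, medians -0.11, 0.13, 0.04 and 0.14). Most of these medians were near 0, and those of antigen presentation, matrix remodelling, integrins, NF-kB targets and CXC, CX3C and XC chemokines changed sign under at least 1 of 6 other scalings. The 17 reference genes, tested in a separate fit, had 0 calls and a median of -0.003.

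The effect of rRELMa was also estimated within each run. In run 1 Arg1 was again the one gene called (log2 fold change -0.55, SE 0.12, edgeR, adjusted p = 0.0395), with 25 genes at an unadjusted p under 0.05. That call was lost after scaling to the reference genes or library totals, with limma on log2 counts, without the filter, and in 7 of 12 fits that left out 1 sample. In run 2, 0 genes were called by edgeR (32 at an unadjusted p under 0.05) and 0 by limma (22 unadjusted). Fitted on the run 2 samples alone, edgeR called 1 gene and not Arg1: Chil4, with a log2 fold change of 0.16 (adjusted p = 0.00135). In the fit with 1 coefficient per group, Arg1 had nearly the same log2 fold change in run 2 as in run 1, -0.56 (SE 0.19, adjusted p = 0.369). The difference of the Arg1 effect between runs was -0.01 (SE 0.23, adjusted p = 0.997). No gene was called for a difference of the effect between runs by edgeR (28 at an unadjusted p under 0.05, smallest adjusted p = 0.479) or limma with a pseudocount of 1 (31 unadjusted). The median SE of this difference was 0.19, against 0.09 in the main comparison, and its recovery was not simulated. A lack of calls thus does not show equal effects. The smallest p for this difference belonged to Ptger2 (-0.63), Vav1 (-0.37), Nlrp3 (-0.90), Mmp8 (-0.44) and Cxcl10 (-1.29) on the negative side. On the positive side they were Ear3 (0.47), Il1rn (0.27), Ctss (0.20), Irf3 (0.54) and Fn1 (0.51). Camera called 0 of 20 lists in run 1, in run 2 and for the difference, with 1, 5 and 4 lists at an unadjusted p under 0.05. Across the 418 genes the log2 fold changes of the runs had a Pearson r of 0.15 and a Spearman rho of 0.16, where genes are not independent replicates.

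**Figure D2:**
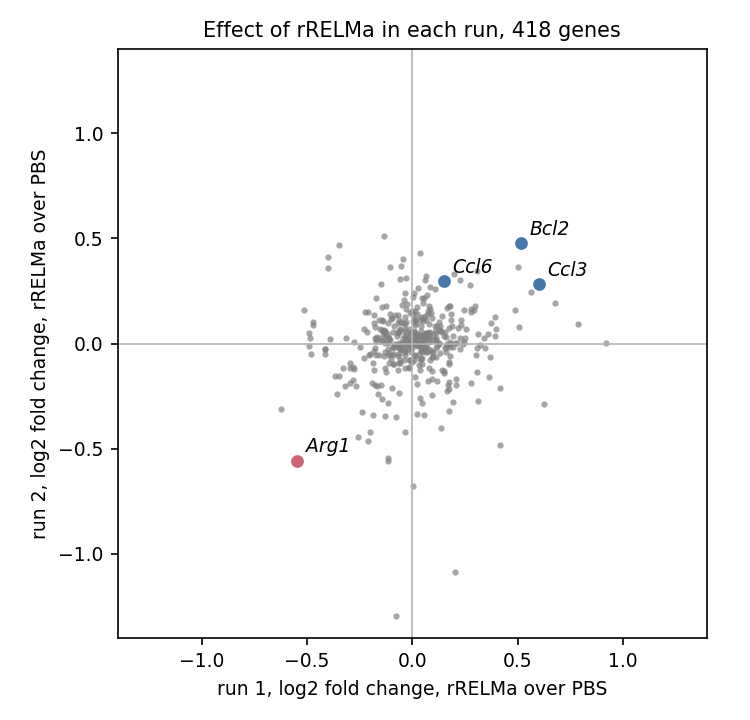
Log2 fold change of rRELMa over PBS in run 1 (horizontal axis) and in run 2 (vertical axis), with 1 point for each of the 418 tested genes. Arg1 (red) lies at -0.55 and -0.56, while Bcl2, Ccl3 and Ccl6 (blue) lie on the positive side in both runs without passing the adjustment.

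Counts differed far more between runs than between treatments. In PBS alone 273 of the 418 genes differed between run 2 and run 1 (edgeR), 124 higher and 149 lower in run 2, and the median absolute log2 difference was 0.45 against 0.06 for the treatment. The runs hold separate samples and the labels do not say what else separated them, so the difference cannot be assigned to biology or to the assay. The assay readings differed too, with 1.67 ± 0.171 (SD, n = 6) endogenous counts per positive-control count in run 1 and 7.54 ± 0.943 (SD, n = 6) in run 2. The split depended on the scaling. It was 52 higher and 217 lower after scaling to the reference genes, 62 and 217 with library totals, 158 and 112 with quantile normalization, 182 and 101 after subtraction of the negative controls, and 369 and 20 with the positive controls. These settings moved the median of all tested genes from -0.03 to -0.37, -0.35, 0.17, 0.28 and 1.59, and the values here are relative to TMM.

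Interferon-stimulated genes were lower in run 2 than in run 1, 11 of 11 tested, with a median log2 difference of -1.92 (camera adjusted p = 1.06e-10, adjusted p = 0.0214 with an estimated correlation). Under the positive-control scaling 2 of the 11 turned positive, Psmb8 and Irf1, and the list's median was -0.30. Isg15, a ubiquitin-like modifier, had 2052 ± 7.05 normalized counts (SD, n = 3) in run 1 PBS and 137 ± 20 (SD, n = 3) in run 2 PBS. Irf7, a transcription factor of the interferon response, had 2039 ± 84.4 (SD, n = 3) and 135 ± 16.7 (SD, n = 3). Of the 17 antigen presentation genes, 15 were lower and 1 higher in run 2 (median -1.06, camera adjusted p = 1.1e-06, adjusted p = 0.0171 with an estimated correlation), although 14 of 17 were positive under the positive-control scaling. Tap1, Psmb8 and Psmb9 belong to both lists. Of the 11 proinflammatory genes 8 were lower and 2 higher (camera adjusted p = 0.0425, adjusted p = 0.241 with an estimated correlation), and of the 9 CC chemokines 6 were lower and 2 higher (0.0334, and adjusted p = 0.28 with an estimated correlation). Both medians turned positive under the positive-control scaling. On the other side, 9 of 13 lipid handling genes were higher in run 2 and 2 lower (camera adjusted p = 0.00184, adjusted p = 0.241 with an estimated correlation), or 8 and 4 after scaling to the reference genes. Of the 10 alveolar macrophage markers 7 were higher and 2 lower (0.0215, and adjusted p = 0.241 with an estimated correlation), or 5 and 4 after scaling to the reference genes and 10 and 0 with the positive controls. Of the 11 lysosome and scavenger genes 5 were higher and 2 lower (0.0422, and adjusted p = 0.203 with an estimated correlation), with a median of 0.17 that turned negative with reference-gene or library-total scaling.

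The genes with the smallest p between runs were, on the lower side, Irf7 (log2 difference -3.89), Isg15 (-3.88), the chemokine Ccl5 (-2.51), the interleukin-1 receptor antagonist Il1rn (-2.36) and the immunoproteasome subunit Psmb8 (-1.43). On the higher side they were the lysosomal protease Ctsd (1.39), the fatty acid transporter Cd36 (1.53), the elastase Mmp12 (1.48), Mrc1 (1.98) and the fatty acid-binding protein Fabp4 (1.60). The direction of these 10 held under 6 other scalings, except that Psmb8 was positive with the positive controls and that Ctsd, among the most abundant genes, showed no difference after quantile normalization. Arg1 was 7.37-fold lower in run 2 PBS than in run 1 PBS (log2 difference -2.88, SE 0.14, edgeR, adjusted p = 4.02e-17). Between treatments the same interferon genes differed little, with a main log2 fold change of -0.07 for Isg15 (SE 0.07) and -0.06 for Irf7 (SE 0.06), neither called.

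**Figure D3:**
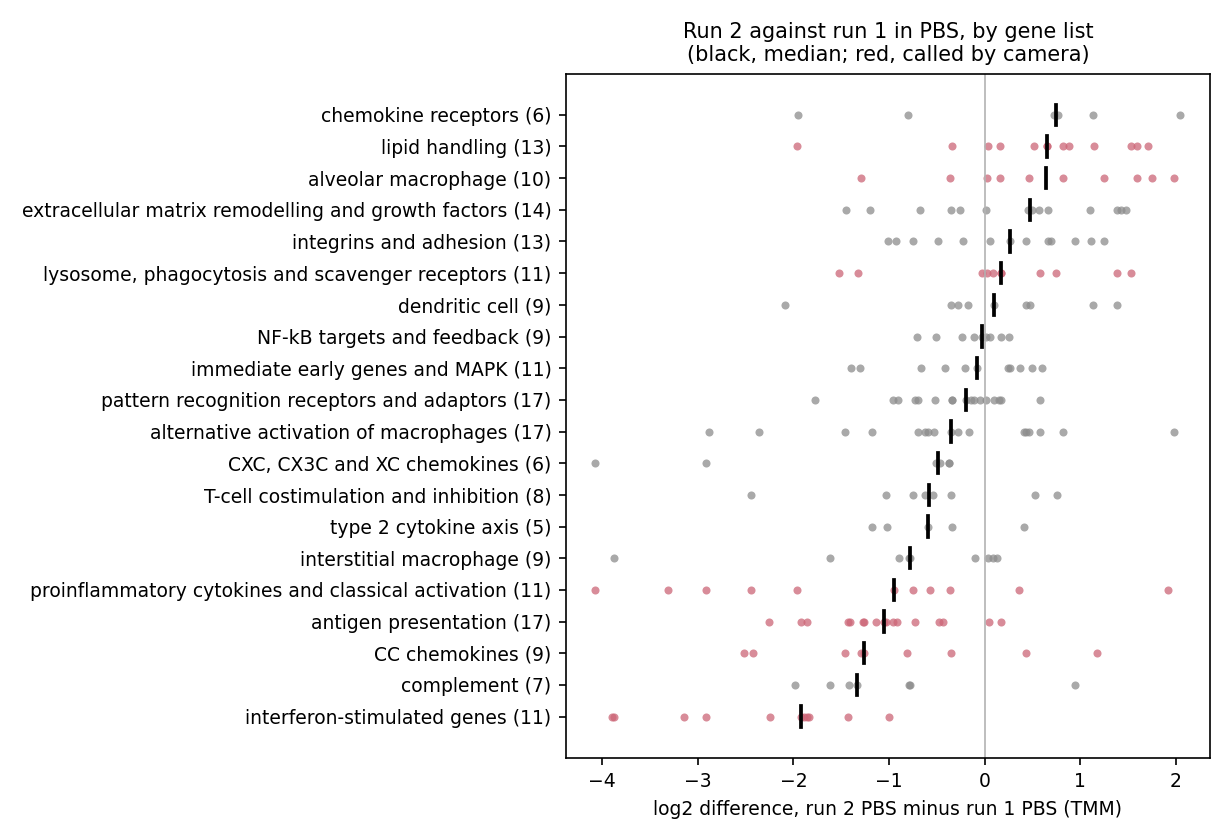
Log2 difference between run 2 PBS and run 1 PBS (horizontal axis) of each tested gene, in the 20 lists with at least 5 tested genes and the number of genes in brackets. Points are genes, black lines are medians and red marks the 7 lists called by camera with its preset correlation. With an estimated correlation 2 lists were called. Interferon-stimulated genes lie lowest, with a median of -1.92, under TMM scaling. With the positive controls 2 of the 11, Psmb8 and Irf1, turn positive.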

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

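Library totals, positive-control scaling, limma with a pseudocount of 1, negative-control subtraction and the negative-control filter were chosen after the data were seen, as were DESeq2 size factors within runs, leaving out samples in the list tests and, for run 2 against run 1 in PBS, all settings but the reference genes and quantiles. Arg1 kept its direction in all 33 other fits of the main comparison (log2 fold change -0.67 to -0.47, adjusted p 0.000482 to 0.998) and was called in 31. The exceptions were the fit without the run (0 genes called, 4 unadjusted) and run 2 alone (adjusted p 0.443), where Chil4 was the 1 gene called (0.16). Without the filter the main count was 2, Arg1 and Fcnb (mean raw count 4.75, at background), and run 2 against run 1 gave 415. DESeq2 called 1 gene, Arg1. In run 1 the count was 0 after scaling to the reference genes or library totals, with limma at either pseudocount and with no filter. With the negative controls subtracted the 1 gene was Ccl3 and not Arg1, and the count was 3 (Arg1, Ctss and Mmp12) with quantile normalization. With quantiles the difference between runs gave 3 genes, Ctss, Mmp12 and Vav1. Fry's mixed test called 3 lists. Psmb8 was reversed between runs with the positive controls (0.19). The cause was not tested.

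Leaving out each sample gave 1 to 1 genes in the main comparison (Arg1 each time), 0 to 1 in run 1, 0 to 0 in run 2 and for the difference, and 252 to 277 between runs in PBS. The run 1 call was lost without run1_rRELMa replicate 1 or 2, run1_PBS replicate 1, 2 or 3, or run2_rRELMa replicate 1 or 3 (0 genes each). Camera called 0 to 1 lists, CC chemokines without run1_PBS replicate 2 or run2_PBS replicate 2.

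Samples with the same number showed no shared deviation. Deviations of same-numbered PBS and rRELMa samples of a run correlated at -0.08 to -0.02 in 6 pairs, and 0 of 12 samples correlated best with their own number. In both runs the positive pairs were PBS 1 with rRELMa 3, PBS 2 with rRELMa 1 and PBS 3 with rRELMa 2 (0.10 to 0.17). A pairing under another numbering was not fitted. The replicate block called 1 gene, Arg1 (log2 fold change -0.54, adjusted p 0.00957), and 0 lists. For Arg1 in the main comparison and the 10 genes with the smallest p between runs, stable by that choice, 289 of 293 fits of other settings kept direction and call, 3 lost the call and 1 reversed. The run 1 call of Arg1 is not among these. Counts near background, such as those of Arg1 in run 2, limit fold changes there: with the negative controls subtracted Arg1 had -0.67.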

Other observations

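Of the tests below, the raw-count test of the interferon pattern, the two-sided count for the correlation between runs and the comparison of cell markers with the SD of their members were chosen only after the results were seen. Genes in the next paragraph were chosen after their values were seen.

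The alternative activation genes held calls in both directions between runs. In PBS 6 of the 17 tested were higher in run 2 and 8 lower, or 3 and 10 after scaling to the reference genes and 13 and 2 with the positive controls, with Mrc1 at 1.98 and Arg1 at -2.88 on the log2 scale, and both held their sign under 6 other scalings. Single genes outside the interferon list were also lower in run 2. The inducible nitric oxide synthase Nos2 was 9.95-fold lower (log2 difference -3.31, adjusted p = 1.61e-18). The Fc receptor Fcgr1 was 14.7-fold lower (-3.87) and Ly6c1, listed here among the monocyte markers, 14.6-fold lower (-3.87). Complement C3 was at -1.99, and 6 of 7 complement genes were lower, although camera did not call that list (adjusted p = 0.0635) and its median turned positive with the positive controls. Siglecf (1.75) was higher in run 2. The raw PBS counts in run 2 were 8 to 12 for Ly6c1 and 8 to 48 for Fcgr1, at or near background, so these fold changes are uncertain.

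The first pattern is the lower Arg1 with rRELMa. Scaling does not explain it, since over 6 other scalings the log2 fold change nearest 0 was -0.54, and neither does a single library, since leaving out each of the 12 samples left it at -0.54 or lower. Loss of a listed cell type would lower that type's markers. The lowest median among lists with 3 or more tested markers was -0.14 for monocytes. It lay above -0.27 by more than its standard error of 0.09. It also lay above the -0.55 of Arg1 by more than the SD of its members, 0.16. This median rests on 4 genes, Ly6c1 (-0.34), Nr4a1 (-0.20), Fn1 (-0.08) and Itgam (0.03). Such medians speak to a type as a whole and cannot show whether a subset with high Arg1 was lost. Of 100 splits within runs 3 called as many genes as the real one, the real one included, a share under the 0.05 set beforehand. Such a count was thus rare among the splits, but 2 other splits called at least 1 gene. The highest other called 2, against 1 in the real split, so chance is not excluded. The splits concern the number of genes called and not Arg1 itself. They also take the samples as independent, which the labels do not establish. A response of the treated cells is a hypothesis. It was not tested apart from a difference between cultures, loss of a subset with high Arg1, or cell types with fewer than 3 tested markers. These stay open.

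For the other counts the splits decide nothing. In run 1 the real count was 1 and the highest other 0 (1 of 10 splits as large), and between runs in PBS it was 273 against 0 (1 of 10), but 10 splits are too few for a share under 0.05. With a real count of 0 every split is as large whatever the data, so there is nothing for the splits to test in run 2 (real 0, highest other 1, 10 of 10), for the difference between runs (real 0, highest other 1, 100 of 100) or for the lists (real 0, highest other 5, 100 of 100). The 5 lists of another split show that groupings other than the treatment can shift lists.

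The second pattern is a weak relation of the rRELMa effects in the runs across genes (r = 0.15, or 0.13 without Arg1). Of the 200 splits within runs 9 gave a correlation as high, the real one included (a share of 0.045), and the highest other was 0.21. This one-sided share was under the 0.05 set beforehand. Swapping the labels of 1 run turns the sign, and counted in both directions 18 of 200 lay as far from 0. That share, 0.09, was above the bound. As the answer depends on the direction counted, no shared effect beyond Arg1 is claimed.

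The third pattern is the higher level of interferon-stimulated genes in run 1. A difference in RNA input or depth does not explain it, since run 2 had the larger totals and yet the raw, unscaled counts of 10 of the 11 genes were lower there, with a median log2 ratio of -0.90 (SE 0.44) and Irf1 as the exception. The list's median of -1.92 stood at percentile 0 of 10000 random lists matched on expression, the lowest of which had -1.41. The low values thus gathered in this list more than in random genes of like expression. The list was singled out because it lay lowest in these same data, so this rank partly restates the pattern. It cannot exclude a difference in probe or reagent lot, which stays open. A different mix of the listed cells stays open: the lowest median of their markers was -0.78 (SE 0.45), for interstitial macrophages, and monocytes had -0.23 (SE 1.46), which met the bound set beforehand, but the members went both ways with SDs of 1.27 and 2.43, wider than their distance to -1.92. Plasmacytoid dendritic cells stay open too, with 2 tested markers (median -2.40). Of these, Irf7 (-3.89) is itself in the interferon list, so that median partly restates the pattern. The other, Tlr9 (-0.90), kept its sign under 5 of 6 other scalings. As what separated the runs is not given in the sources used here, no biological explanation was tested.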
